A study of Homo sapiens with 12 samples.

How the data were processed

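Gene expression was measured on 12 Affymetrix GeneChip arrays of the human cell line MDA-MB-231, an established line of triple-negative breast cancer, after 24 h with the vehicle DMSO or with rotenone, digoxin or manassantin, with 3 arrays in each of the 4 groups. Groups and replicate numbers were taken from the sample titles. The titles name digoxin where the series' design text names digitoxin, a related cardiac glycoside, so which of these cells received is open; the titles' name is used throughout. The design text names the third compound as manassantin A. Doses and the oxygen level during treatment are not given in the sources used here. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

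Per the labels, RNA was extracted with a column kit, amplified, labelled with biotin and hybridized. The deposited values are probe set summaries that were read as log2 intensities, already on a common scale by the authors; the method of background correction, summarisation and normalization is not given in the sources used here. The log2 base was inferred from the range of the values, 1.655 to 13.75, with array medians from 5.881 to 5.995. The values were not centred per gene. The table held 22277 probe sets, of which 62 were controls. A platform annotation gave 1 gene symbol for 19064 probe sets, several for 1043 and none for 2108, and genes were named only from the first kind. Of these, 19052 matched a current gene record, 12 did not and kept the annotation's symbol, and 0 were renamed. Each gene was represented by its probe set with the highest mean over all arrays, which gave 11963 genes, 4310 of them with several probe sets. Genes with no such probe set, among them HSPA8, HSPA1A and CA9, were not analysed here. The number of arrays limits the precision of each value.

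Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 12 arrays, group as the only term, 8 residual degrees of freedom and a prior worth 3.68. Adjusted p-values are Benjamini-Hochberg values within a comparison over the 11963 genes, and genes under 0.05 are called. Fold changes are log2 differences of group means with the model's standard error (SE). No filter on dim genes was used; a gene is called dim where its mean lies under the 40th percentile of all genes, a log2 value of 5.747. Before the data were examined, 30 gene lists were fixed from textbook knowledge and tested with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists within a comparison. Each list was tested again with a correlation estimated from the data. The genes named here were also set by a rule fixed then: the 8 called genes with the largest rise and the 8 with the largest fall against DMSO, 5 and 5 between compounds, up to 4 leading members of a described list, and a fixed set of genes tied to the study's topic. Several lists share members. The glycolysis genes SLC2A1, SLC2A3, HK2, PFKFB3, ALDOA, ALDOC, TPI1, GAPDH, PGK1, ENO1, ENO2 and LDHA are also in the hypoxia list. Shifts of the glycolysis and hypoxia lists are therefore not independent. DDIT4 is in both the hypoxia and the ATF4 lists.

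On simulated data with 200 of the 11963 genes changed between manassantin and DMSO, in 20 simulations, the procedure recovered 50.4% of genes changed by 0.3 on the log2 scale, 90.8% at 0.5 and 99.9% at 1, and 5.2% of calls were false. Simulated values were drawn independently for each gene and array, without quality differences or effects shared by a replicate number. The real calls may therefore hold a different share of false ones. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

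The groups share replicate numbers. Deviations of arrays from their group means were correlated across genes. For rotenone and manassantin the same-numbered arrays correlated at 0.107 to 0.362. Each was over 0.1, so the numbers met a criterion for pairing set beforehand. The labels do not say what the number marks, and rotenone replicate 3 correlated more with a differently numbered manassantin array. Alternatives tried were the replicate number as a block, quantile normalization, median centring, leaving out dim genes, the mean of a gene's probe sets, every probe set, a trended robust prior, array weights, a fit on only the groups compared, leaving out each array in turn, and for lists an estimated correlation and fry. Further alternatives were chosen after seeing the data: a covariate made from the spike-in poly-A controls' 3' minus 5' difference, a covariate made from the 18S rRNA control, and leaving out replicate 1 of every group, because those arrays had the smallest such difference.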

Results

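MDA-MB-231 cells were profiled after 24 h with 1 of 3 compounds or the vehicle DMSO, on 3 arrays per group. Manassantin is a plant lignan, rotenone an inhibitor of respiratory complex I that also binds tubulin, and digoxin a cardiac glycoside that blocks the sodium pump. The study's title places the compound in hypoxia, Hsp90 activity and chaperone-mediated autophagy, so genes of those processes were among the fixed lists. All values are log2 expression of 1 probe set per gene, with no transcript count behind them.

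Manassantin against DMSO asked which transcripts the compound moved. TXNIP, a thioredoxin-binding protein that restrains glucose uptake, fell by 0.97 ± 0.053 (SE, n = 3 arrays per group) on the log2 scale, from 10.97 ± 0.0819 (SD) to 10.0 ± 0.0443 (adjusted p = 7e-06). The largest rises were of the collagenase gene MMP1 (0.78 ± 0.12), of CYP1A1 (0.69 ± 0.10), of SCG5 (0.61 ± 0.076) and of ALAS1 (0.59 ± 0.052, adjusted p = 0.00074), which encodes the first enzyme of heme synthesis. CYP1B1, like CYP1A1 a target of the aryl hydrocarbon receptor, rose by 0.51 ± 0.051, and CLMN by 0.56, SPAG4 by 0.51 and PLAT, tissue plasminogen activator, by 0.46. Lower genes included ID2 at -0.43, FAM13B at -0.36, TFRC, the transferrin receptor, at -0.36 and SMAD4 at -0.33, and the dim genes TAF4B (-0.44), ZNF334 (-0.36) and TRIM52 (-0.36). For CLMN, ID2 and SMAD4 the gene's other probe set did not pass.

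Of the hypoxia and HIF-1 target list, 9 of 34 measured genes rose and 0 fell, or 17 and 0 adjusted over the list alone (median log2 fold change 0.207, camera adjusted p = 4.19e-12, and adjusted p = 0.0135 with an estimated correlation). NDRG1 rose by 0.41 and LOX, a collagen cross-linking enzyme, by 0.38, while VEGFA stood at 0.32 (adjusted p = 0.0544). HIF1A itself differed by -0.02 (adjusted p = 0.896). Of 20 glycolysis genes 3 rose and 0 fell (adjusted over the list alone, 7 and 0), with SLC2A3 at 0.29 and ENO2 at 0.27, and the list shifted up with camera adjusted p = 0.000182 (adjusted p = 0.0429 with an estimated correlation). SLC2A3, ENO2 and many other members are also in the hypoxia list, so this shift is not independent of that list's. With the 18S control as a covariate, chosen after seeing the data, the glycolysis median went from 0.0843 to 0.0309. The 32 genes of G2/M and mitosis lay lower as a group, with a median of -0.138 and camera adjusted p = 4.19e-11 (adjusted p = 0.0135 with an estimated correlation). No single mitotic gene was called over all genes by limma, where 1896 genes reached an unadjusted p under 0.05. Adjusted over the list alone 13 were lower, and DLGAP5 stood at -0.27 (adjusted p = 0.0507). On the same arrays the spike-in dap control, a measure of 3' bias in the target, had a 3' minus 5' difference of 3.069 ± 0.493 (SD, n = 3) with manassantin and 2.493 ± 0.395 with DMSO. The difference was 0.576 (exact permutation test, two-sided, p = 0.2, where 3 against 3 cannot go below 0.1). The same difference of the thr control was higher by 0.394 with manassantin (exact p = 0.3), and the 18S rRNA control was lower by 0.87 (SD 0.505 with manassantin and 0.337 with DMSO, n = 3 each, exact p = 0.2), the largest difference among the control measures tested.

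Smaller shifts of 3 other lists were called by camera at the preset correlation, and none of the 3 passed fry. Lysosomal genes had a median of 0.0888 with 0 of 36 called and 0 in either direction adjusted over the list alone (camera adjusted p = 0.00686, and adjusted p = 0.519 with an estimated correlation). Interferon-stimulated genes had a median of 0.0815 with 0 of 30 called and 9 higher adjusted over the list alone (camera adjusted p = 0.00754, and adjusted p = 0.519 with an estimated correlation). Ribosome biogenesis genes had a median of -0.0449 with 0 of 24 called and 4 lower adjusted over the list alone (camera adjusted p = 0.00518, and adjusted p = 0.519 with an estimated correlation). Of 16 measured components of chaperone-mediated autophagy 0 were called, also adjusted over the list alone, with a median of 0.0051 (camera adjusted p = 0.943). LAMP2 stood at 0.08 and HSP90AA1 at -0.05. Of 22 heat shock and Hsp90 chaperone genes 0 were called, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.454). In the ATF4 list TXNIP was the 1 called gene of 42, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.171). Of 25 mesenchymal and matrix genes 4 rose, among them MMP1 and ITGA5 (0.44), with 7 higher adjusted over the list alone, but the list did not pass (camera adjusted p = 0.0989, and adjusted p = 0.519 with an estimated correlation). That result depended on the processing, as the list passed in 7 of 17 alternatives other than the estimated correlation and fry.

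In total 116 of 11963 genes were called, 102 higher and 14 lower, and 0 of them changed by 2-fold or more in either direction. The split was less one-sided in some settings, with 70 higher and 34 lower for every probe set. It was 372 and 119 with dim genes left out and 361 and 142 with a trended robust prior. Median centring left it at 66 and 10. The 3 arrays of each group did not overlap for 22.4% of genes, where chance gives 10%. The count rested on every array. It was 25, 10 and 7 without DMSO replicate 1, 2 or 3, and 13, 11 and 9 without manassantin replicate 1, 2 or 3. It was 4 in a fit on these 6 arrays alone, 76 with median centring, 278 with array weights, 491 with dim genes left out and 503 with a trended robust prior, so single calls near the threshold are uncertain. With the 18S control as a covariate, chosen after seeing the data, it was 2, TXNIP and CYP1B1: all 116 genes kept their direction and the median fold was 0.945 of its main value, while the median standard error rose from 0.0537 to 0.0852. TXNIP, ALAS1, SCG5, CYP1B1 and SPAG4 passed with each of the 6 arrays left out, MMP1 in 1 of the 6 and CYP1A1 in 2.

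**Figure D1:**
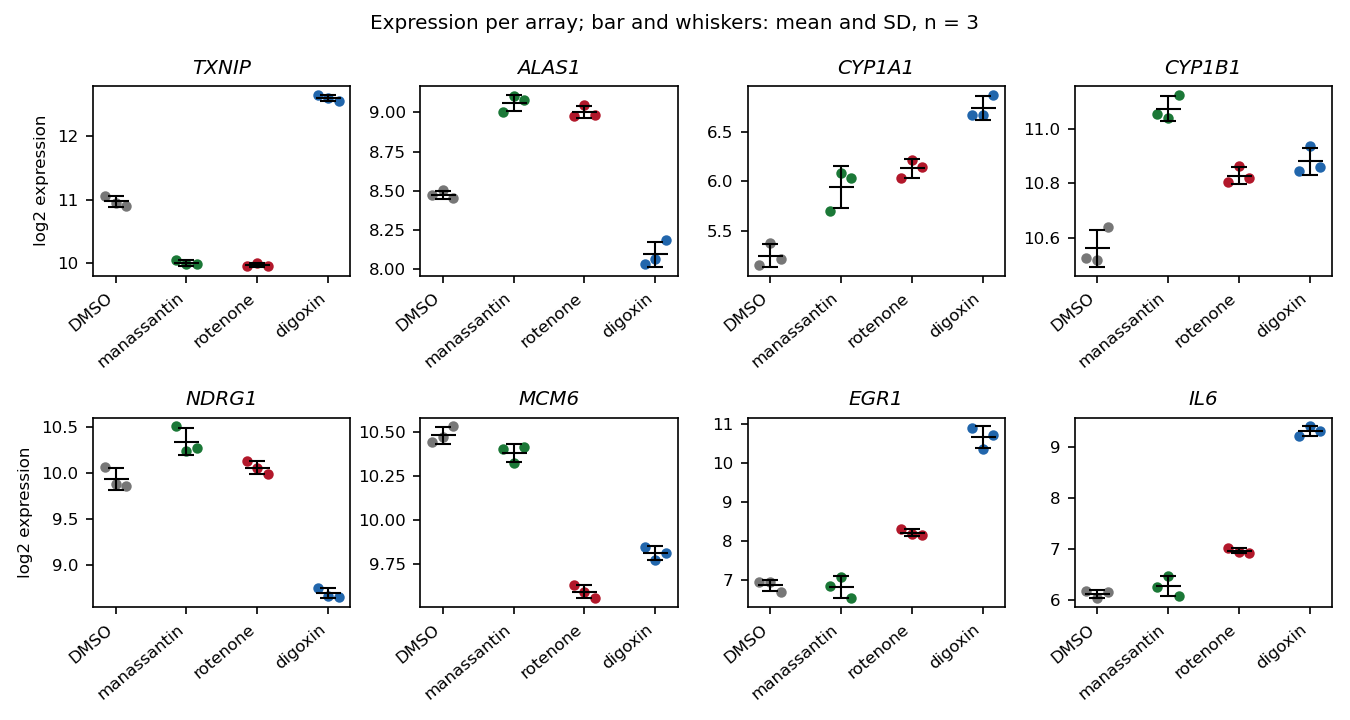
Log2 expression of 8 genes on each array (dots, n = 3 per group), with the group mean and SD as bar and whiskers; the vertical scales differ and do not start at 0. TXNIP is lower with manassantin (10.0) and rotenone (9.968) than with DMSO (10.97), while the digoxin arrays lie above all others.

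Rotenone against DMSO asked which transcripts that compound moved, on the same vehicle arrays. Whether the changes run through complex I was not tested. The histone gene H2BC21 rose by 2.27 ± 0.085, from 4.667 to 6.934, although its mean over all arrays was dim. The transcription factor gene NR4A2 rose by 1.5 ± 0.17, IL24 by 1.5 ± 0.13, EGR1 by 1.35 ± 0.15 and the chemokine gene CXCL2 by 1.11 ± 0.089. MMP1 (1.03), SCG5 (0.92) and CYP1A1 (0.88) rose as well. TXNIP fell by 1.0 ± 0.053 and MCM6, a subunit of the replicative helicase, by 0.89 ± 0.048, each with adjusted p = 2.04e-06. UNG, a uracil-DNA glycosylase, stood at -0.79, CCNE2, a cyclin of the G1/S transition, at -0.78 and LACTB2 at -0.73, and the dim genes PPFIBP2 (-1.07), LIPG (-0.97) and NDP (-0.82) were also lower. For EGR1 the gene's other probe set did not pass.

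Genes of G1/S and DNA replication fell together: 26 of 34 were lower and 0 higher, or 31 lower adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.96e-37, and adjusted p = 0.001 with an estimated correlation). Genes of G2/M and mitosis moved the other way, with 10 of 32 higher and 2 lower, and 13 and 2 adjusted over the list alone (camera adjusted p = 1.02e-06, and adjusted p = 0.0358 with an estimated correlation). CDC20 rose by 0.51 and AURKA, a mitotic kinase gene, by 0.47, while CDK1 was lower at -0.29 and NUSAP1 at -0.24. The control measures moved in the same directions as with manassantin: 18S was lower by 0.434 (SD 0.172 with rotenone and 0.337 with DMSO, exact p = 0.2), and the 3' minus 5' difference was higher by 0.191 for dap (exact p = 0.7) and by 0.246 for thr (exact p = 0.5).

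Of 30 immediate early genes 16 rose and 0 fell (17 and 2 adjusted over the list alone; camera adjusted p = 2.94e-11, and adjusted p = 0.0358 with an estimated correlation). Of 25 NF-kB and inflammatory cytokine genes 10 rose and 0 fell (12 and 1 adjusted over the list alone), with IL6 at 0.85 (camera adjusted p = 1.83e-07, and adjusted p = 0.0511 with an estimated correlation). Among 22 heat shock and Hsp90 chaperone genes 3 rose, with HSPB8 at 0.55 and DNAJB4 at 0.32, and 9 were higher adjusted over the list alone (camera adjusted p = 6.76e-05, and adjusted p = 0.0358 with an estimated correlation). Fatty acid synthesis genes shifted down, with 3 of 11 lower and 5 lower adjusted over the list alone. SCD, a fatty acid desaturase, stood at -0.68 and the regulator SREBF1 at -0.43 (camera adjusted p = 0.00189, and adjusted p = 0.0473 with an estimated correlation).

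For 6 further lists the camera call was lost with an estimated correlation. In the ATF4 list 8 of 42 genes fell and 2 rose (15 and 2 adjusted over the list alone), with CHAC1 at -0.54 and ASNS, asparagine synthetase, at -0.26 against ATF3 at 0.78 and PPP1R15A at 0.42 (camera adjusted p = 0.000362, and adjusted p = 0.175 with an estimated correlation). Of ribosome biogenesis genes 5 of 24 rose, NOP2 and BYSL by 0.31 each, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.7e-05, and adjusted p = 0.259 with an estimated correlation). Of interferon-stimulated genes 4 of 30 fell, RSAD2 at -0.41 and IFIT3 at -0.32 among them, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00603, and adjusted p = 0.336 with an estimated correlation). In the hypoxia list 6 of 34 rose and 2 fell (7 and 2 adjusted over the list alone), with ADM at 0.56 and BHLHE40 at 0.48 against CA12 at -0.66 and DDIT4 at -0.46 (camera adjusted p = 0.0345, and adjusted p = 0.336 with an estimated correlation). Lysosomal genes had 4 of 36 higher, also 4 adjusted over the list alone, NEU1 at 0.43 and NPC1 at 0.28 (camera adjusted p = 0.0131, and adjusted p = 0.446 with an estimated correlation). Mitochondrial ribosomal proteins had 2 of 40 higher and 1 lower, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.472 with an estimated correlation).

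Rotenone changed 830 genes, 425 higher and 405 lower, of which 6 rose and 2 fell by 2-fold or more. Groups did not overlap for 31.2% of genes. The count was 500, 371 and 426 without DMSO replicate 1, 2 or 3 and 463, 346 and 485 without rotenone replicate 1, 2 or 3. It was 1301 with dim genes left out, 1312 with a trended robust prior, 1614 with array weights and 323 with the 18S covariate. With that covariate all 830 genes kept their direction, and the median ratio of their folds to the main ones was 0.986. The median standard error rose from 0.0592 to 0.0699.

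Digoxin against DMSO had the largest changes of the 3 compounds. Whether they run through the sodium pump was not tested. EGR1 rose by 3.81 ± 0.15, the interleukin gene CXCL8 by 3.69 ± 0.098, IL11 by 3.21 ± 0.15 and IL6 by 3.21 ± 0.088. IL24 (3.14), ABL2 (3.01), the hyaluronan synthase gene HAS2 (2.82) and CXCL2 (2.49) followed. The largest falls were of IDH1, cytosolic isocitrate dehydrogenase, at -3.44 ± 0.12, of KRCC1 at -3.38 ± 0.18 and of PNMA8A at -2.90. DDIT4, an inhibitor of mTORC1 signalling, stood at -2.77, ID1 at -2.70 and SLCO4A1 at -2.57, with the dim genes SH3TC2 at -3.01 and NXPE3 at -2.86. TXNIP rose by 1.64 ± 0.053, HIF1A was lower at -0.33 and NDRG1 at -1.24.

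NF-kB and inflammatory cytokine genes were higher for 19 of 25 and lower for 1, IRF1 at -0.29, with the same counts adjusted over the list alone (median 0.804, camera adjusted p = 2.41e-07, and adjusted p = 0.124 with an estimated correlation). Immediate early genes were higher for 23 of 30 and lower for 2, or 24 and 2 adjusted over the list alone (camera adjusted p = 7.96e-07, and adjusted p = 0.124 with an estimated correlation). Macroautophagy genes were higher for 20 of 27 and lower for 3, with the same counts adjusted over the list alone, ATG12 at 1.22 and GABARAPL1 at 1.08 (camera adjusted p = 0.00166, and adjusted p = 0.124 with an estimated correlation). Interferon-stimulated genes were lower for 20 of 30 and higher for 4, with the same counts adjusted over the list alone, IFIT1 at -2.47 and IFIT3 at -1.92 (camera adjusted p = 5.12e-05, and adjusted p = 0.18 with an estimated correlation). In the hypoxia list 23 of 34 were lower and 4 higher, or 23 and 6 adjusted over the list alone, with MXI1 at -1.60 against ADM at 2.23 (camera adjusted p = 0.000362, and adjusted p = 0.129 with an estimated correlation).

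Fatty acid synthesis genes were lower for 9 of 11, also 9 adjusted over the list alone, SCD at -1.58 (camera adjusted p = 0.00822, and adjusted p = 0.124 with an estimated correlation). Heat shock and Hsp90 chaperone genes were lower for 13 of 22 and higher for 5, with the same counts adjusted over the list alone, HSPB1 at -0.78 and DNAJA1 at -0.75 against HSPA4L at 0.55 (camera adjusted p = 0.037, and adjusted p = 0.197 with an estimated correlation). In the ATF4 list 25 of 42 were lower and 11 higher, with the same counts adjusted over the list alone, XPOT at -1.63 and ASNS at -1.28 against PPP1R15A at 2.41 (camera adjusted p = 0.0241, and adjusted p = 0.325 with an estimated correlation). Ribosome biogenesis genes were higher for 14 of 24 and lower for 3, or 15 and 3 adjusted over the list alone, DDX10 at 1.41 and RRP12 at 1.14 (camera adjusted p = 0.00879, and adjusted p = 0.438 with an estimated correlation). Lysosomal genes were higher for 19 of 36 and lower for 4, with the same counts adjusted over the list alone, NPC1 at 1.06 against ASAH1 at -0.75 (camera adjusted p = 0.037, and adjusted p = 0.471 with an estimated correlation). Of all 30 lists, 10 were called by camera and 0 with an estimated correlation, although fry, which tests a list by itself and not against other genes, called 26.

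Digoxin changed 6561 genes, 3347 higher and 3214 lower, with 172 higher and 555 lower by 2-fold or more. The direction of small changes depended on the scale. The median over all genes was 0.0651, and centring each array on its median moved it to 0.152 and the split of calls to 5020 higher and 2685 lower. Groups did not overlap for 61.9% of genes. With digoxin too 18S was lower, by 0.364 (SD 0.134 with digoxin and 0.337 with DMSO, exact p = 0.2), and the 3' minus 5' difference was higher by 0.252 for dap (exact p = 0.4) and by 0.331 for thr (exact p = 0.3).

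**Figure D2:**
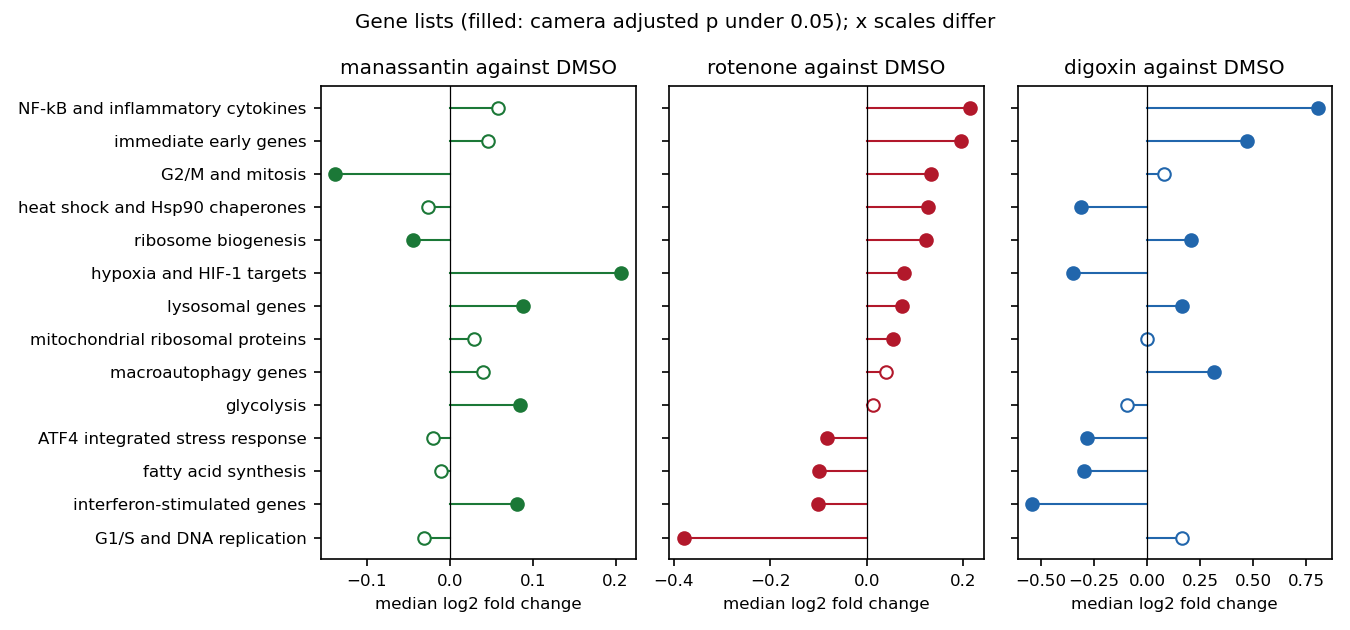
Median log2 fold change of each gene list that camera called in at least 1 comparison with DMSO, for the 3 compounds; filled points passed camera's adjusted p of 0.05, and the horizontal scales differ. Mitotic genes lie at -0.138 with manassantin and 0.133 with rotenone, and replication genes at -0.38 with rotenone.

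Manassantin against rotenone tested the difference between these compounds directly. Replication genes were higher with manassantin: HELLS, a chromatin remodeller, by 0.86 ± 0.099, MCM6 by 0.79 ± 0.048 and MCM5 by 0.77 ± 0.047. Of the G1/S and DNA replication list 28 of 34 were higher and 0 lower, or 32 and 0 adjusted over the list alone (camera adjusted p = 6.55e-31, and adjusted p = 0.00201 with an estimated correlation). Mitotic genes were lower for 21 of 32 and higher for 2, or 23 and 2 adjusted over the list alone, with AURKA at -0.64 and PLK1 at -0.61 (camera adjusted p = 1.39e-16, and adjusted p = 0.00349 with an estimated correlation). H2BC21 (-2.52), NR4A2 (-1.69), EGR1 (-1.40), FOS (-1.1, dim) and ID2 (-1.09) had the largest differences downward, while SCD (0.72) and the dim gene ARHGEF4 (0.72) were among the largest upward. None of the other probe sets of SCD and ARHGEF4 passed. Heat shock and Hsp90 chaperone genes were lower with manassantin for 7 of 22, or 10 adjusted over the list alone, HSPB8 at -0.44 and CHORDC1 at -0.37 (camera adjusted p = 6.32e-06, and adjusted p = 0.0228 with an estimated correlation). For TXNIP the difference was 0.03 ± 0.053 (adjusted p = 0.765).

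Hypoxia genes were higher with manassantin than with rotenone for 8 of 34 and lower for 1, or 9 and 2 adjusted over the list alone, DDIT4 at 0.55 and CA12 at 0.52 against ADM at -0.48 (camera adjusted p = 0.000249, and adjusted p = 0.0919 with an estimated correlation). Interferon-stimulated genes were higher for 6 of 30, or 13 adjusted over the list alone, IFI44 at 0.35 (camera adjusted p = 1.19e-07, and adjusted p = 0.0732 with an estimated correlation). Ribosome biogenesis genes were lower for 11 of 24, or 16 adjusted over the list alone, DDX21 at -0.35 (camera adjusted p = 3.95e-11, and adjusted p = 0.0732 with an estimated correlation). Immediate early genes were lower for 15 of 30 and higher for 3, or 17 and 3 adjusted over the list alone (camera adjusted p = 4.74e-09, and adjusted p = 0.0671 with an estimated correlation). NF-kB genes were lower for 8 of 25, or 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.0919 with an estimated correlation). Glycolysis genes had 1 of 20 higher and 2 adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.104 with an estimated correlation). The ATF4 list had 9 of 42 higher and 2 lower, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0423, and adjusted p = 0.385 with an estimated correlation).

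The comparison called 1013 genes, 561 higher and 452 lower with manassantin, of which 0 were higher and 6 lower by 2-fold or more. The count was 603, 500 and 505 without rotenone replicate 1, 2 or 3 and 510 and 602 without manassantin replicate 1 or 3, and 1540 with dim genes left out, 1545 with a trended robust prior and 390 with the 18S covariate. With that covariate all 1013 genes kept their direction, and the median ratio of their folds to the main ones was 0.987. The median standard error rose from 0.0598 to 0.0708. The values of this comparison come from the fit with group as the only term, although the replicate numbers met the pairing criterion for these groups. With the replicate number as a block 1352 genes were called, 763 higher and 589 lower with manassantin.

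Manassantin against digoxin was likewise tested directly. IDH1 (3.62 ± 0.12), KRCC1 (3.26 ± 0.18), SH3TC2 (2.99, dim), SLCO4A1 (2.95) and PNMA8A (2.94) were higher with manassantin, and EGR1 (-3.85 ± 0.15), CXCL8 (-3.47), IL11 (-3.20), HAS2 (-3.19) and IL6 (-3.05) lower. TXNIP stood at -2.61 ± 0.053 and NDRG1 at 1.65. Hypoxia genes were higher with manassantin for 24 of 34 and lower for 4, with the same counts adjusted over the list alone (camera adjusted p = 2.58e-06, and adjusted p = 0.113 with an estimated correlation). Interferon-stimulated genes were higher for 23 of 30 and lower for 2, or 24 and 2 adjusted over the list alone (camera adjusted p = 2.06e-06, and adjusted p = 0.113 with an estimated correlation). NF-kB genes were lower for 18 of 25 and higher for 1, or 19 and 1 adjusted over the list alone (camera adjusted p = 1.72e-06, and adjusted p = 0.113 with an estimated correlation). Camera called 5 lists up and 5 down at the preset correlation and 0 with an estimated one. In all 6781 genes were called, 3363 higher and 3418 lower, with 602 higher and 172 lower by 2-fold or more. Median centring moved the split to 2797 higher and 5047 lower.

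The responses were also set against each other across genes, which are not independent replicates. Fold changes against DMSO correlated at 0.35 between manassantin and rotenone, at 0.00985 between manassantin and digoxin and at 0.4 between rotenone and digoxin (leave-one-out errors 0.166, 0.127 and 0.0366). The value for manassantin and digoxin has no settled sign, as it was -0.0777 without manassantin replicate 2 and 0.1 without manassantin replicate 1. Because all 3 use the same DMSO arrays, unchanged groups with a shared control were simulated. Each draw took deviations from group means on arrays of all groups, with random signs, and used 3 of them as the control. It was thus not built on the DMSO arrays themselves, so its range is only approximate for them. The simulated correlation was 0.49 (central range -0.0156 to 0.807, with the most extreme draws at each end left out). The covariance was 0.00628, 0.000579 and 0.0299 in the same order, against 0.00416 in the simulation (central range -7.99e-05 to 0.00861). Only that of rotenone and digoxin lay outside this central range. Of the called genes, 31 rose with both manassantin and rotenone where independent lists would share 3.62, and 4 fell with both where 0.474 would. ID2 fell with manassantin and rose with rotenone (0.66). Manassantin and digoxin shared 33 rises (28.5 for independent lists) and 9 falls (3.76), and 48 genes rose with manassantin and fell with digoxin (27.4). Rotenone and digoxin shared 275 rises (119) and 242 falls (109). In 50 draws of unchanged groups 0 calls were shared for each pair, but those draws called on average only 0.02 genes for manassantin, 1.66 for rotenone and 0 for digoxin, so that 0 says nothing about lists as long as the observed ones. Lists of the observed lengths were therefore also taken from the same draws, as the genes with the smallest p in each direction, a check chosen after seeing the data. For manassantin and rotenone these shared a median of 42 rises (range 2 to 93) and 11 falls (1 to 14). The medians were 86.5 rises (0 to 102) and 13.5 falls (0 to 14) for manassantin and digoxin, and 341 rises (87 to 424) and 313 falls (98 to 402) for rotenone and digoxin. Each observed number of genes shared in the same direction lies below its median and inside its range, but these lists hold only the noise that the shared arrays give and no effects, so they set no bound on genes called in both. Part of each excess of genes shared in the same direction may still come from the shared DMSO arrays. Noise in those arrays moves both fold changes the same way. It would therefore not raise the number of genes, 48, that rose with manassantin and fell with digoxin. The 27.4 for independent lists, however, takes every gene as equally likely to be called. Of the 116 genes called with manassantin, 109 were also called with dim genes left out. In that setting digoxin called 2860 genes lower and 2380 higher. Calls were thus not spread evenly over genes, 27.4 may be too low, and 48 against 27.4 does not establish opposed responses.

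**Figure D3:**
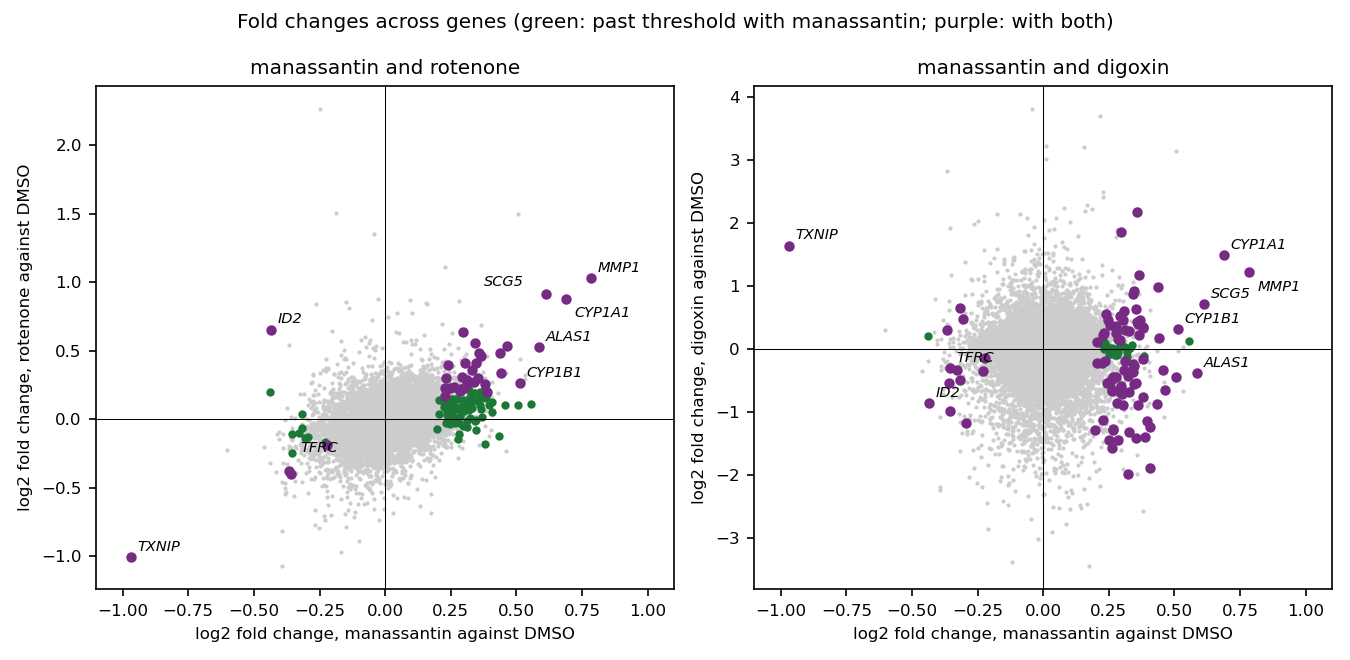
Log2 fold change of each gene against DMSO with manassantin (horizontal) and with rotenone or digoxin (vertical), 1 point per gene; green genes passed the adjusted p of 0.05 with manassantin and purple genes with both compounds. TXNIP lies at -0.97 with manassantin and -1.0 with rotenone but at 1.64 with digoxin, and ID2 falls with manassantin and rises with rotenone.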

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

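Probe sets that the annotation ties to no gene or to several genes entered no comparison of the report, and they were looked at because they hold signal outside it. Of these 3151 probe sets, 4 were higher and 4 lower with manassantin than with DMSO by limma at an adjusted p under 0.05, 52 and 48 with rotenone, and 744 and 535 with digoxin.

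Control probe sets were compared after their values had been seen. The hybridization control bioB, which is added after labelling and does not come from the cells, was above all 3 DMSO arrays on all 3 arrays of digoxin, by 0.12, and of manassantin, by 0.141 (exact permutation test, two-sided, p = 0.1 for each, the smallest that 3 against 3 allows). Of the 15 such checks made, 2 came out this way, where chance at 5% each would give 0.75.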

How the results depend on the processing

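The covariates from the spike-in controls and from the 18S control and the omission of replicate 1 were chosen after seeing the data. Over the alternatives, named genes kept their side of the threshold in 7971 of 8759 recomputed values, lost the call in 687, gained it in 98 and reversed in 3. A change of sign was counted only where the gene was called in either fit, so uncalled genes may have changed sign uncounted. Stability differed between comparisons: for manassantin against DMSO, 5 to 10 of 25 called named genes were kept with single arrays left out. Lists kept the call in 821 of 912, lost it in 91 and reversed in 0. The reversals came with the mean of a gene's probe sets: SP100 became -0.2005 for digoxin against DMSO and 0.2326 for manassantin against digoxin, and PSMD12 became 0.3094 for manassantin against digoxin. Both have probe sets that disagree. The count for manassantin against DMSO, 116, was 76 with median centring, 291 with the replicate block, 491 with dim genes left out, 503 with a trended robust prior, 278 with array weights, 4 in the fit on only these groups, 2 with the 18S covariate and 1 without replicate 1 in any group. Rotenone against DMSO, 830, became 1301 with dim genes left out, 1312 with the trended robust prior, 1614 with array weights, 323 with the 18S covariate and 265 without replicate 1. Manassantin against rotenone, 1013, became 1540 with dim genes left out, 1545 with the trended robust prior, 390 with the 18S covariate and 226 without replicate 1. With the 18S covariate all 116 genes of manassantin against DMSO kept their direction and the median fold went from 0.315 to 0.299. The median standard error rose from 0.0537 to 0.0852, as 18S differs between these groups and the covariate takes up part of the comparison, so calls ended mainly through the wider error. Leaving out single arrays gave 7 to 25 genes for manassantin against DMSO, 346 to 500 for rotenone against DMSO and 500 to 835 for manassantin against rotenone. Fewer arrays leave fewer degrees of freedom. Leaving out dim genes lowers the number tested and also changes the genes behind the variance prior, and these were not separated. The trended robust prior, with all genes tested, gave similar counts, so a smaller number of tests is not needed for such a rise. For the other settings the cause was not tested. Digoxin's counts stayed within 1.5 times. The replicate block gave 1352 genes for manassantin against rotenone, where the numbers met the pairing criterion of each over 0.1. The other pairs of groups did not meet it. Their same-numbered arrays correlated at -0.0347 to 0.0771 for DMSO and manassantin, 0.0339 to 0.185 for DMSO and rotenone, 0.0795 to 0.158 for DMSO and digoxin, 0.0531 to 0.0943 for rotenone and digoxin and 0.0508 to 0.143 for digoxin and manassantin. In all but the first of these pairs the same-numbered array gave the highest value in its row for all 3 numbers, so a weaker sharing by number is not ruled out there. For rotenone and manassantin it did so for replicates 1 and 2 but not for 3. The correlation of rotenone and digoxin responses, 0.4, moved to 0.363 with the spike-in covariate, by more than its leave-one-out error. Among the alternatives other than the estimated correlation and fry, the hypoxia, glycolysis, G2/M and ribosome biogenesis calls for manassantin against DMSO held in 17 of 17, although the glycolysis median went from 0.0843 to 0.0309 with the 18S covariate. Hypoxia, glycolysis and G2/M also passed the estimated correlation and fry. Ribosome biogenesis passed neither (camera adjusted p = 0.519 with an estimated correlation, fry adjusted p = 0.136). The other called lists of that comparison lost the call in part: interferon-stimulated genes passed in 14 of 17 and lysosomal genes in 15, with a highest adjusted p of 0.202 each. Neither passed fry (fry adjusted p = 0.0887 and 0.106). For rotenone against DMSO hypoxia genes passed in 10 of 17, interferon-stimulated genes, lysosomal genes and mitochondrial ribosomal proteins in 15 each, and fatty acid synthesis in 16. For digoxin against DMSO lysosomal genes passed in 12, heat shock and Hsp90 chaperones in 13, fatty acid synthesis in 15 and ATF4 in 16. For manassantin against rotenone the ATF4 list passed in 9 and glycolysis in 14. For manassantin against digoxin NRF2 targets passed in 12, fatty acid synthesis in 15 and glycolysis in 16. All remaining called lists passed in 17 of 17. Signal over background was not given, so dim genes have no known limit here.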

Other observations

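Tests chosen after the values were seen are those of TXNIP's other probe sets, of the tubulin, histone, BMP and SMAD and iron lists, of the spike-in and 18S covariates for TXNIP and for the hypoxia and mitotic lists, and of same-numbered arrays for those lists; the 6 lists tested below were all drawn up after the leading genes were known. Genes that had prompted a list were taken out of it after a first run: that moved the BMP and SMAD result from lower to undecided, and it lowered the histone median. A rule was also changed after the values were seen: a list whose median went against a hypothesis at first excluded it, and was later read as undecided unless camera passed in the opposite direction, which changed the reading of the KRAB zinc finger list. The values of same-numbered arrays took the place of a test by the replicate block and were first read as arguing against a shared batch. Neither tests it, because a shift shared by a number cancels in a balanced design. The range of unchanged groups for disjoint DMSO arrays was added after the covariances were seen. It was first read by a share of draws under 0.05 and then, once that share was known, by the central range, which changed the reading of the shared DMSO arrays from argued against to undecided.

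Histone genes without H2BC21, H1-2 and H2AC6 were higher with digoxin for 21 of 30 and lower for 0, with a median of 0.56 (camera p = 3.19e-07, adjusted p = 3.19e-06 over the 30 tests of 6 lists in 5 comparisons, and p = 0.0169 with an estimated correlation). With rotenone 5 of the 30 were higher and 0 lower. With manassantin the list went the other way against DMSO, with a median of -0.0655 and 0 of 30 called (camera p = 0.0098, adjusted p = 0.042, and p = 0.168 with an estimated correlation). Against rotenone 8 were lower with manassantin and 0 higher, with a median of -0.0778 (camera adjusted p = 0.00011, and p = 0.0359 with an estimated correlation), and against digoxin 24 were lower and 0 higher, with a median of -0.578 (camera adjusted p = 1.03e-06, and p = 0.0122 with an estimated correlation). Histone genes are near-identical copies whose probes can cross-hybridize, so single members are uncertain. Tubulin genes differed between manassantin and rotenone, with 5 of 12 higher with manassantin and 0 lower, a median of 0.133 and camera p = 6.85e-08 (adjusted p = 1.03e-06 over the 30 tests, and p = 0.0144 with an estimated correlation). Against DMSO the tubulin median was 0.119 with manassantin, with 1 of 12 higher (camera p = 1.1e-05, adjusted p = 8.25e-05, and p = 0.0349 with an estimated correlation), and -0.101 with rotenone, with 2 of 12 lower (camera p = 0.0125, adjusted p = 0.0469, and p = 0.187 with an estimated correlation). The rotenone part is thus the weaker one; tubulin copies can cross-hybridize as well.

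TXNIP was lower with manassantin and rotenone and higher with digoxin. Failure or cross-hybridization of 1 probe set is argued against, since the gene's other 2 probe sets passed in the same direction in all 6 tests. With the spike-in 3' minus 5' difference as a covariate the highest adjusted p of the 3 comparisons was 0.000149 (over all alternatives the adjusted p of these comparisons ranged from 7.24e-18 to 0.00467), which argues against a 3' to 5' gradient of target quality as the whole cause. With the 18S control as a covariate the highest adjusted p was 0.00277, at a fold of -0.986 (SE 0.0856) against -0.969 (SE 0.0529) without it for manassantin, which argues against a quality difference seen in 18S as the whole cause. A biological response of TXNIP that differs between compounds remains a hypothesis consistent with these values, found and tested on the same data.

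With manassantin, hypoxia genes lay higher and mitotic genes lower. A 3' to 5' gradient of target quality as the whole cause is argued against, since with the spike-in covariate the smaller of both lists' medians was 0.827 of its main value and both calls held. With the 18S control as a covariate the smaller ratio was 0.877 and both calls held. This argues against a quality difference seen in 18S as the whole cause of these list shifts. Most single gene calls of this comparison ended with that covariate. The glycolysis list, which shares members with the hypoxia list, was not part of this test. Its median went from 0.0843 to 0.0309 with the same covariate. For glycolysis genes a quality difference seen in 18S is therefore not argued against. A single array as the cause of the hypoxia and mitotic shifts is argued against too, since the smallest ratio over the 6 arrays left out was 0.87. With the covariates and with arrays left out, camera was run only at its preset correlation, not with an estimated one. That the calls held is therefore weak evidence, and these arguments rest on the medians. A shift shared by all arrays of a number cancels in the fold change by design, so no test of it was made. Differences between same-numbered manassantin and DMSO arrays are given as a description: they had hypoxia medians of 0.195, 0.173 and 0.228 and mitotic medians of -0.0749, -0.158 and -0.127 for replicates 1, 2 and 3. The smallest ratio to the main median was 0.543. A batch acting differently on the groups cannot be told apart from the compound, with 1 array per group and number. A biological effect of the compound stays open as well, and whether it runs through HIF-1 or through growth was not tested.

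Whether fold changes with manassantin and with rotenone moved together beyond their shared DMSO arrays is undecided. Their correlation was 0.35 and their covariance 0.00628, against 0.49 and 0.00416 (central range -7.99e-05 to 0.00861) for unchanged groups. With disjoint DMSO arrays the covariance was above 0 in 6 of 6 ways, the lowest 0.00177. In 1000 draws of unchanged groups the central range of that lowest value was -0.00852 to 0.00248, with 41 draws as high as observed (a share of 0.041), so the observed value lies inside the range. Lying above 0, the bound set beforehand, was too weak, as unchanged groups reach 0.00248, and the shared DMSO arrays are not excluded. With disjoint DMSO arrays and also different replicate numbers it was above 0 in 5 of 6 ways and -0.00189 in the other. A batch shared by arrays of the same number therefore cannot be told apart from a common response. For these compounds the numbers met the pairing criterion, and too few arrays remain to separate batch from response.

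Hypotheses about single gene groups were tested on the added lists, and a list counted for a hypothesis where camera's unadjusted p at the preset correlation was under 0.05. Loss of microtubules lowers tubulin mRNAs, and rotenone binds tubulin: the tubulin median with rotenone was -0.101, barely past the -0.1 set as the limit (camera p = 0.0125, adjusted p = 0.0469 over the 30 tests, and p = 0.187 with an estimated correlation), so this may be weak, and it does not account for the rise with manassantin. A general rise of aryl hydrocarbon receptor targets may accompany CYP1A1 and CYP1B1 with manassantin: the other targets had a median of 0.124, with 1 of 8 higher (camera p = 0.0497, adjusted p = 0.149, and p = 0.103 with an estimated correlation), which fails the correction. A general rise of histone transcripts with rotenone had a median of 0.0571 (camera p = 0.0081, adjusted p = 0.0405, and p = 0.158 with an estimated correlation). A fall of BMP and SMAD targets with digoxin, beyond ID1 and ID2, was not seen as a shift of the list: the median was 0.0372 while camera's direction was down (limma's camera adjusted p = 0.381 over the 30 tests), with 4 of 11 lower and 1 higher. Loss of KRAB zinc finger transcripts with digoxin was left undecided by a median of 0.0377, with 21 of 65 higher and 19 lower (limma's camera adjusted p = 0.987). A fall of iron uptake genes beyond TFRC with manassantin was left undecided by a median of -0.00742 over 8 genes (limma's camera adjusted p = 0.987).

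Each comparison of 6 arrays has 10 splits into 3 and 3, too few for a share under 0.05. The real split called 116 genes for manassantin against DMSO and the highest of the other splits 0; the values were 830 and 0 for rotenone, 6561 and 0 for digoxin, 6781 and 0 for manassantin against digoxin, and 1013 and 1 for manassantin against rotenone, so 1 split of 10, the real one, reached the real count each time. For that last comparison, 3 other splits also part all 3 pairs of same-numbered arrays, and those called 0. Every split other than the real one, however, puts arrays of both groups on each side. Any difference between the groups, from the compound or from a batch, then widens the spread within the sides and lowers the calls. The low counts of these splits are therefore no measure of what unchanged groups would give, and no conclusion is drawn from them.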
